A study of Mus musculus with 47 samples.

How the data were processed

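Striatal RNA from 47 mice aged 6 months was sequenced by the authors as stranded TruSeq libraries on an Illumina instrument. The mice fell into 6 genotype groups: wild type, Q140, Ccdc82+/-, Ccdc82-/-, Q140 Ccdc82+/- and Q140 Ccdc82-/-. Q140 mice carry a copy of Htt with an expanded CAG repeat and serve as a model of Huntington's disease. Groups, sexes, replicate numbers and plate wells were taken from the sample labels. No library was left out of the comparisons.

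The deposited table of counts holds raw read counts per gene, 1 column per library and 48795 genes, of which 33998 had at least 1 count in any library. The deposited FPKM table holds values that the authors scaled by gene length and by the total counts of the library. Each FPKM value equalled the count divided by the column total and by 1 length per gene, with a largest relative deviation of 2.5e-13. The submitters' notes name STAR 2.7.5c, SAMtools 1.10 and HTSeq 0.12.3 with the builds GRCm38 and mm10. They do not state settings or the annotation release. Gene positions were taken from GENCODE release M21, which held 48435 of the gene identifiers.

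Total counts ranged from 41.3 to 61.7 M per library, with a median of 47.7 M. At this depth the median 95% confidence half-width of a log2 fold change between 2 groups was 0.083 to 0.087. For an interaction it was 0.118 to 0.121. These medians cover the 13938 genes with a mean log2 of scaled counts (counts per M counts, CPM) of at least 1. Intervals cover the spread between libraries as modelled, and PCR duplicates could not be told apart from independent molecules.

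Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr on the 6 groups, which left 19193 genes, and libraries were scaled by the trimmed mean of M values (TMM). Dispersions were estimated with estimateDisp and a robust quasi-likelihood model was fitted with 1 coefficient per group and a sex term over all 47 libraries. Contrasts were tested with glmQLFTest, and genes passed at a Benjamini-Hochberg adjusted p under 0.05. The 11 contrasts were Q140 against its control on 3 Ccdc82 backgrounds, Ccdc82+/- and Ccdc82-/- each with and without Q140, 2 interactions, and the average Ccdc82+/- and Ccdc82-/- effect over both Htt genotypes. A second model with 12 coefficients, 1 per genotype and sex, tested whether the Q140 and the Ccdc82-/- effect differed between sexes, on 19714 genes. Log2 fold changes are given with their standard error (SE), and CPM with the standard deviation (SD) between libraries. Adjusted p-values come from edgeR unless another tool is named.

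The groups, contrasts, tests, named-gene rule, 26 gene lists and most alternatives were fixed before the data were examined. Named genes were the 10 with the largest rise and the 10 with the largest fall among genes past the threshold with a mean log2 CPM of at least 1. From each list the up to 4 genes with the smallest p in Q140 against wild type were added. Ccdc82, Htt, the C57BL/6 substrain genes Nnt, Wdfy1 and Entpd4, the genes past the threshold within 5 Mb of Ccdc82, and Xist, Ddx3y, Uty, Kdm5d and Eif2s3y completed the rule. A few genes that the rule selects are not reported here. The lists cover shared, direct pathway and indirect pathway markers of medium spiny neurons (MSN), and markers of striatal interneurons, homeostatic and reactive astrocytes, microglia, oligodendrocytes, their precursors, and endothelial and mural cells. Markers of cortical excitatory neurons, thalamic or pallidal neurons, choroid plexus, ependymal cells and blood stood for tissue that a dissection can carry along. The other lists cover cholesterol biosynthesis, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, immediate early genes, heat shock and chaperone genes, the unfolded protein and integrated stress response, mismatch repair and Huntington's disease modifier genes, p53 targets, clustered protocadherins, developmental transcription factors and the interferon response.

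Lists were tested with camera from limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and adjustment over the 26 lists of a comparison. The same test with the correlation estimated from the data, and fry, were run beside it. After the list tests had been seen, the mean log2 CPM of each list per library was also compared by an exact two-sided permutation test, adjusted over the 26 lists. The Q140 signature score of a library was the mean log2 CPM of the genes that rose minus that of the genes that fell with Q140 on the Ccdc82 background left out of the test. Scores and Ccdc82 levels were compared by exact two-sided permutation tests, with 95% intervals from 10000 bootstrap resamples. Differences of differences used 100000 permutations.

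Alternatives were RLE size factors, the Wald test of DESeq2 1.42.0, voom with quality weights, no filter on low counts, no sex term, the replicate number as a block, the plate column as a factor, a fit of only the groups compared, each sex alone, and limma-trend on log2(FPKM + 0.1) for genes with an FPKM of at least 0.5 in 7 or more libraries. Fits without 3 libraries whose marker levels stood apart, and with the number in the sample identifiers as a random block, were added after the data had been seen. Random regroupings of the libraries numbered 100 per pair of groups and 60 per interaction, average or sex effect, the real grouping included. The models were tested on simulated data in which genes with a mean log2 CPM of at least 1 were changed by known amounts. In the Ccdc82-/- against wild type setting with 19067 genes, edgeR recovered 88.1% of genes changed 1.2-fold, 95.5% at 1.5-fold and 98.5% at 2-fold. At 1.2-fold it recovered 79.1% for Ccdc82+/- and 74.6% for Q140, each against wild type. It recovered 82.1% for Q140 Ccdc82-/- against Q140 and 64.2% for the interaction with Ccdc82-/-. Simulated genes varied independently and many changed at once, so these rates need not hold for a single changed gene. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.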

Results

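Gene expression was measured by RNA sequencing in the striatum of 47 mice aged 6 months. The wild type, Q140, Ccdc82+/-, Ccdc82-/- and Q140 Ccdc82+/- groups held 8 mice each, 4 of each sex. The Q140 Ccdc82-/- group held 7 mice, 3 females and 4 males. Total counts per library ranged from 41.3 to 50.1 M in wild type, 43.8 to 61.7 in Q140, 44.6 to 58.6 in Ccdc82+/-, 42.4 to 51.5 in Ccdc82-/-, 42.8 to 58.8 in Q140 Ccdc82+/- and 42.2 to 55.7 in Q140 Ccdc82-/-. Mitochondrially encoded transcripts took 5.71% ± 0.131 (SD, n = 8) of counts in wild type and 6.03% ± 0.112 (SD, n = 8) in Q140. Xist and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y matched the sex label of all 47 libraries: the lowest Xist level in 23 females was 1174 CPM and the highest in 24 males was 1.07 CPM.

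Ccdc82 (ENSMUSG00000079084), the targeted gene, lies on chromosome 9 from 13246955 to 13292520 in GRCm38. Its mRNA fell in steps with the number of copies targeted by the label, both with and without the Q140 allele. Wild type mice had 12.01 CPM ± 0.773 (SD, n = 8), Ccdc82+/- mice 8.42 ± 0.519 (n = 8) and Ccdc82-/- mice 4.57 ± 0.666 (n = 8), an exact permutation p of 0.000155 for each step. These levels were 70.1% (95% interval 66.3 to 74.4) and 38.03% (34.5 to 42.2) of wild type. Q140 mice had 11.6 CPM ± 0.950 (n = 8), Q140 Ccdc82+/- mice 8.61 ± 0.927 (n = 8) and Q140 Ccdc82-/- mice 4.56 ± 0.652 (n = 7), with an exact permutation p of 0.000155 for each step. The last 2 stood at 74.0% (67.8 to 80.7) and 39.2% (35.0 to 43.6) of Q140. The Ccdc82+/- level differed from the midpoint of its neighbours by 0.131 CPM (95% interval -0.343 to 0.610) without Q140 and by 0.511 CPM (-0.197 to 1.22) with it. Q140 alone left Ccdc82 at 96.9% of wild type (exact permutation p = 0.391, n = 8 per group). Counts per gene do not show whether the mRNA that remains in Ccdc82-/- mice lacks a part of the transcript or makes protein, so a copy called lost here is a copy targeted by the label.

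**Figure D1:**
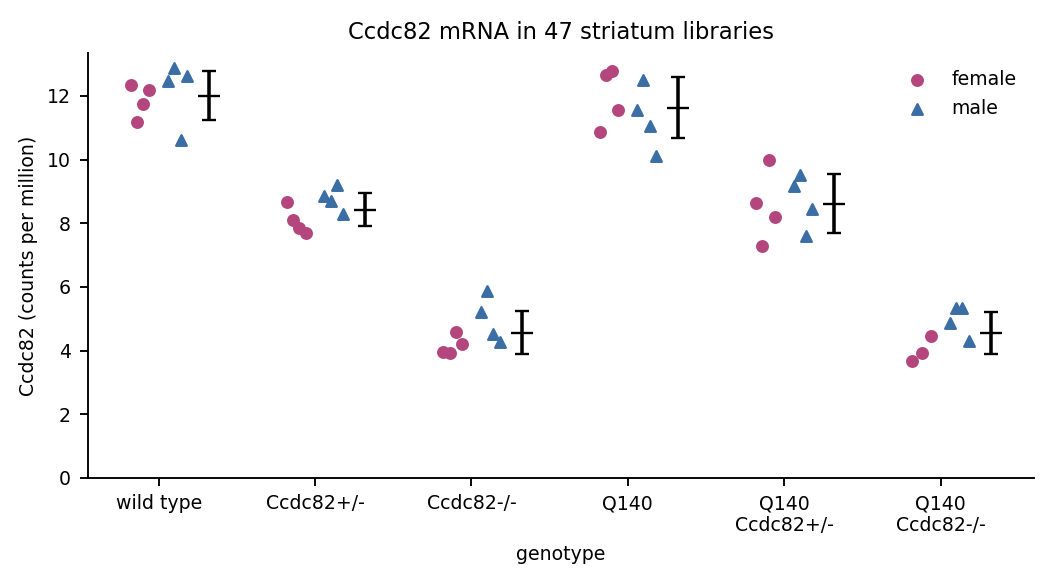
Ccdc82 mRNA in CPM for each library by genotype, with circles for females, triangles for males and a bar for the group mean ± SD. Every Ccdc82-/- library without Q140 lies at or below 5.87 CPM, and every wild type library lies at or above 10.6 CPM.

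The comparison of Q140 with wild type asked how the expanded Htt allele changes striatal expression. The strongest call was Penk (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819), which encodes the enkephalin precursor of indirect pathway neurons. It fell from 1679 CPM ± 77.9 (SD, n = 8) to 823.9 ± 67.8 (n = 8), a log2 fold change of -1.03 ± 0.04 (SE, adjusted p = 5.18e-25). Pde10a, a phosphodiesterase of medium spiny neurons, fell by 0.81 on the log2 scale, and the dopamine receptor genes Drd1 and Drd2 fell by 0.57 and 0.55. Most of the clustered protocadherins tested, adhesion molecules encoded in gene clusters, rose. Of 19193 genes tested, 6655 passed the threshold (34.7%), 3485 higher and 3170 lower in Q140. The split depends on processing: with the deposited FPKM values, scaled by total counts and filtered to 16451 genes, 5829 were higher and 1958 lower. Most changes were small: 176 of the genes changed by at least 1 on the log2 scale, 56 upward and 120 downward, while 51.4% changed by less than 0.2. Htt itself (ENSMUSG00000029104, chromosome 5, 34761740 to 34912534) fell from 217.0 CPM ± 9.36 to 199.0 ± 12.1 (n = 8 each, log2 fold change -0.13 ± 0.03, adjusted p = 0.000462). With females alone its change of -0.10 did not pass. Plate columns were unevenly spread, with 4 of the 8 wild type libraries and 0 of the Q140 libraries in column 4, and 5755 genes passed with the column as a factor. Females alone gave 4321 genes and males alone 3922.

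Among genes past the threshold with a mean log2 CPM of at least 1, the largest rise was that of Sfmbt2, a Polycomb protein gene, at 1.88 ± 0.12 log2 units (SE). Dsp, which encodes the junction protein desmoplakin, followed at 1.69 ± 0.21. Gm6089 rose by 1.65, the protocadherin Pcdh20 by 1.44, AW551984 by 1.31, Tmc3 by 1.28 and Rprm by 1.26. Tnnt2, the troponin T gene of heart muscle, rose by 1.22, Fam196b by 1.22 and Greb1l by 1.13. The largest fall among these genes was that of Gpx6, a glutathione peroxidase gene, at -2.47 ± 0.17. Mafa, a transcription factor gene, stood at -2.29 ± 0.14, and the Wnt ligand genes Wnt8b and Wnt4 at -2.28 and -1.67. Cpne9 fell by 1.995, Plk5 by 1.77, Sec14l3 by 1.77, Slc4a11 by 1.66, Gm9754 by 1.64 and Ddit4l by 1.59.

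**Figure D2:**
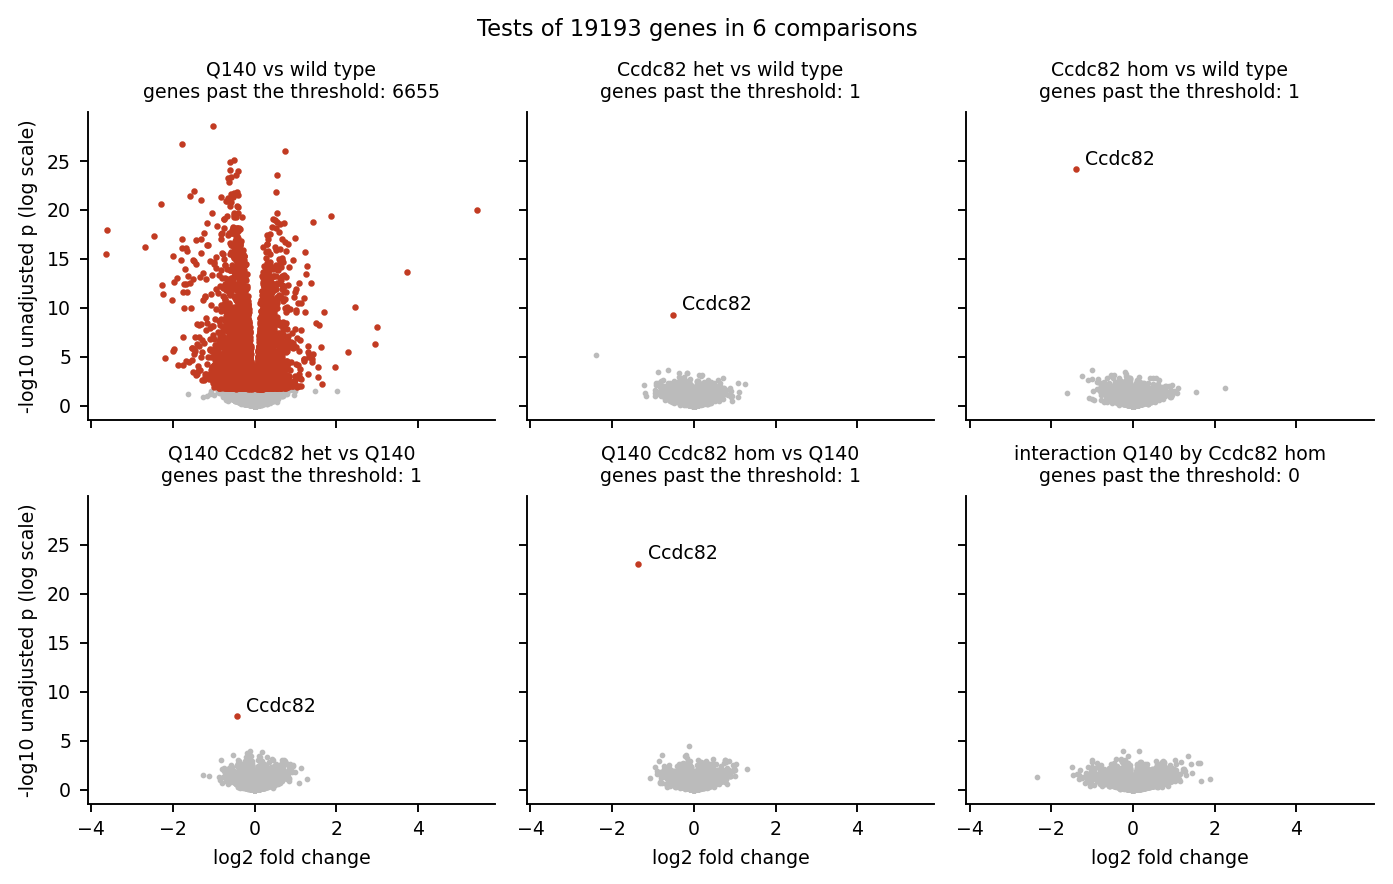
Log2 fold change against -log10 unadjusted p for 19193 genes in 6 comparisons, with genes past an adjusted p of 0.05 in red. Q140 against wild type has 6655 such genes, each of the 4 Ccdc82 comparisons has Ccdc82 alone, and the interaction with Ccdc82-/- has 0.

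Genes that mark medium spiny neurons, the main neurons of the striatum, fell in Q140. All 24 shared MSN identity genes fell, also when adjusted over the list alone, with a median log2 change of -0.46. Examples were Pde1b at -0.57 ± 0.03 (SE), the adenylyl cyclase gene Adcy5 at -0.63 ± 0.03 and Ddit4l at -1.59 ± 0.09. The list passed camera (adjusted p = 2.99e-35) and, in the fit of all 47 libraries, also with an estimated correlation (adjusted p = 0.00272). Of 8 measured indirect pathway genes 5 fell and 3 did not pass, or 6 fell when adjusted over the list alone, and the median was -0.57. Beside Penk these included the adenosine receptor gene Adora2a at -0.75 ± 0.05, Drd2 at -0.55 ± 0.04 and the receptor gene Gpr6 at -0.59 ± 0.05. This list passed camera (adjusted p = 7.96e-08) and in the same fit with an estimated correlation (adjusted p = 0.0139). The direct pathway list moved both ways: 3 of 10 genes rose and 3 fell, or 3 and 4 adjusted over the list alone. Drd1 stood at -0.57 ± 0.03 and the muscarinic receptor gene Chrm4 at -0.55 ± 0.05, while Isl1, a transcription factor gene of these neurons, rose by 0.37 ± 0.04 and Tac1, the substance P precursor gene, by 0.17 ± 0.04. Its median was 0.03, its mean -0.05 and its camera direction down (adjusted p = 0.697), while fry (adjusted p = 0.00733) and an exact permutation test of the list mean per library (-0.045, p = 0.0204, adjusted p = 0.0481 over 26 lists, n = 8 per group) passed. Of 12 striatal interneuron genes 2 fell, Nos1 at -0.15 and Kit at -0.11, also over the list alone (camera adjusted p = 0.430).

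Clustered protocadherins were the group that rose most broadly. Of 53 genes 32 rose, 2 fell and 19 did not pass, or 33 and 3 adjusted over the list alone, with a median of 0.30. Pcdhb3 rose by 0.83 ± 0.08 (SE), Pcdhga4 by 0.64 ± 0.06, Pcdhb9 by 0.62 and Pcdhb22 by 0.59. The list passed camera (adjusted p = 3.17e-10) and with an estimated correlation in the fit of all libraries (adjusted p = 0.00545). In a fit of the Q140 and wild type libraries alone, 0 lists passed with an estimated correlation, so the calls of the MSN identity, indirect pathway and protocadherin lists with it were lost there. Their means per library differed by -0.57, -0.48 and 0.29 (exact permutation p = 0.000155 for each, n = 8 per group). Immediate early genes, which neurons switch on with activity, fell: 14 of 21, or 15 adjusted over the list alone, with a median of -0.48. Egr2 stood at -1.46 ± 0.27, Npas4 at -0.80 ± 0.16, Dusp1 at -0.68 and Homer1 at -0.64. The camera call (adjusted p = 0.000262) was lost with an estimated correlation (adjusted p = 0.645). The list mean per library was lower in Q140 by an exact permutation test, at -0.49 log2 units (p = 0.000932, adjusted p = 0.00404 over 26 lists, n = 8 per group).

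Lists of glial and vascular markers shifted by small amounts. Of 16 homeostatic astrocyte genes 7 fell and 1 rose, the same over the list alone, with a median of -0.09. The bicarbonate transporter gene Slc4a4 stood at -0.30 ± 0.04 (SE), Atp1b2 at -0.28, the glutamate transporter gene Slc1a2 at -0.19 and S100b at 0.15. The camera call (adjusted p = 0.00693) was lost with an estimated correlation (adjusted p = 0.601). Of 19 microglia genes 6 fell, or 9 adjusted over the list alone, with a median of -0.10. Cd68 stood at -0.17, the complement gene C1qc at -0.13, Laptm5 at -0.10 and Cx3cr1 at -0.12, and the camera adjusted p of 0.0164 became an adjusted p of 0.645 with an estimated correlation. Of 17 endothelial and mural genes 7 fell, or 8 over the list alone, with a median of -0.13. The smooth muscle gene Tagln stood at -0.73 ± 0.10, the VEGF receptor gene Kdr at -0.41, Rgs5 at -0.20 and Pdgfrb at -0.13. Their camera adjusted p of 0.00880 became an adjusted p of 0.443 with an estimated correlation. Exact permutation tests of the list means per library gave -0.12 for homeostatic astrocyte genes (p = 0.00839), -0.09 for microglia (p = 0.000311) and -0.17 for endothelial and mural genes (p = 0.000777), with n = 8 per group. The size of these falls depends on scaling: with the deposited FPKM values the medians shrank to -0.032, -0.03 and -0.077 in the same order.

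The remaining cell type lists did not pass camera. Of 18 reactive astrocyte genes 1 rose, H2-D1 at 0.17, and 1 fell, Fbln5 at -0.65, or 0 and 1 over the list alone (camera adjusted p = 0.583). Of 17 oligodendrocyte genes 5 fell, also over the list alone, among them Aspa at -0.29 (camera adjusted p = 0.377). Of 9 precursor genes Olig1 and Lhfpl3 rose, by 0.17 and 0.15, and Vcan fell by 0.27 (camera adjusted p = 0.956). Over the list alone these were 2 and 2. Of 12 cortical excitatory neuron genes 3 rose, among them Cux2 by 0.26 and Lamp5 by 0.26, and 3 fell, or 3 and 4 over the list alone. The median of that list was -0.18 and its mean -0.14 while its camera direction was up (adjusted p = 0.956). Among 6 thalamic or pallidal genes Ntng1 rose by 0.28, also over the list alone, and the median of -0.01, the mean of 0.07 and the camera direction, up, differed in sign (adjusted p = 0.913). Among 10 choroid plexus genes Clic6 rose by 0.27, also over the list alone, the median was -0.63 and the camera adjusted p 0.583. The choroid plexus mean per library differed by -0.53 on the log2 scale (exact permutation p = 0.00513, n = 8 per group). Wild type male 1 stood apart in it at 0.76, where the other wild type libraries lay at -0.46 to 0.06. For Q140 on the Ccdc82+/- background the choroid plexus median was 0.18. On the Ccdc82-/- background, which holds a male with high choroid plexus markers, it was -0.94. None of 7 ependymal and 5 blood genes passed, over all genes or over the list alone, with camera adjusted p-values of 0.583 and 0.913. The ependymal median was -0.24, and the blood median of 0.05 and mean of -0.01 differed in sign.

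For genes of energy metabolism, DNA repair and stress responses the direction differed between lists. Of 80 nuclear oxidative phosphorylation genes 29 rose and 4 fell, also over the list alone, with a median of 0.05. The ATP synthase genes Atp5g1 and Atp5b rose by 0.26 and 0.15, Uqcrfs1 rose by 0.14 and the complex I gene Ndufs3 fell by 0.23, and the camera adjusted p of 0.00693 became an adjusted p of 0.971 with an estimated correlation, while the list mean per library rose by 0.035 (exact permutation p = 0.0143, n = 8 per group). Of 13 mitochondrially encoded genes mt-Co1 rose by 0.07 and mt-Atp8 and mt-Atp6 fell by 0.29 and 0.21, also over the list alone (camera adjusted p = 0.583). Of 14 mismatch repair and Huntington's disease modifier genes 5 rose and 0 fell in edgeR, also over the list alone. These included Rrm2b at 0.25 and the mismatch repair genes Msh6 at 0.16 and Mlh3 at 0.14. The camera adjusted p of 0.0375 became an adjusted p of 0.601 with an estimated correlation, and the list mean per library rose by 0.07 (exact permutation p = 0.0160, n = 8 per group). Of 24 cholesterol biosynthesis genes 4 rose and 5 fell, also over the list alone, with Acat2 at -0.46, Msmo1 at -0.31 and Ebp at 0.15 (camera adjusted p = 0.583). Of 17 chaperone genes Hspa8 rose by 0.27 and Hsf1 fell by 0.13, or 1 and 0 over the list alone (camera adjusted p = 0.697). Of 19 unfolded protein and integrated stress response genes 4 rose and 2 fell, also over the list alone, with Asns at 0.21 and Trib3 at -0.93. The median of this list was 0.02 and its mean -0.02, with a camera direction of up (adjusted p = 0.697). Of 19 p53 targets 5 rose and 2 fell, also over the list alone: Eda2r rose by 0.73, Aen by 0.16, and Cdkn1a and Plk2 fell by 0.61 and 0.22 (camera adjusted p = 0.583).

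Wt1, Onecut1 and Hoxa7, transcription factor genes of early development, were near silent in wild type striatum and higher in Q140. Wt1 rose from 0.092 CPM ± 0.063 (SD, n = 8) to 1.29 ± 0.635, Onecut1 from 0.035 ± 0.029 to 0.302 ± 0.150 and Hoxa7 from 0.098 ± 0.058 to 0.296 ± 0.083. Of 31 measured genes of this list 4 rose and 3 fell, or 3 and 1 over the list alone. Its median was -0.10 and its mean 0.17, with a camera direction of down (adjusted p = 0.956). The list mean per library was 0.135 higher in Q140 (exact permutation p = 0.0412, adjusted p = 0.082 over 26 lists, n = 8 per group). By that test the list passed, upward, for Q140 on the Ccdc82+/- and Ccdc82-/- backgrounds. Of 23 interferon response genes 1 rose and 1 fell, also over the list alone, with Ifi27l2a lower by 2.02 ± 0.23 (SE) (camera adjusted p = 0.583). Of the substrain genes Wdfy1 fell by 0.15 (adjusted p = 0.0192), and Nnt stood at -0.08 and did not pass. Entpd4 had too few counts to be tested.

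With the deposited FPKM values, which are scaled by total counts, the median change of all genes was 0.06 and the medians of the interneuron, oligodendrocyte, oligodendrocyte precursor, cholesterol, mitochondrially encoded, developmental transcription factor, interferon and thalamic lists turned from below 0 to above 0. The FPKM fit also used another gene filter, which left 16451 genes, so scaling need not be the only reason. With RLE factors the medians of these lists stayed below 0. The number of lists past camera with the preset correlation was 9, and 3 with an estimated correlation.

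**Figure D3:**
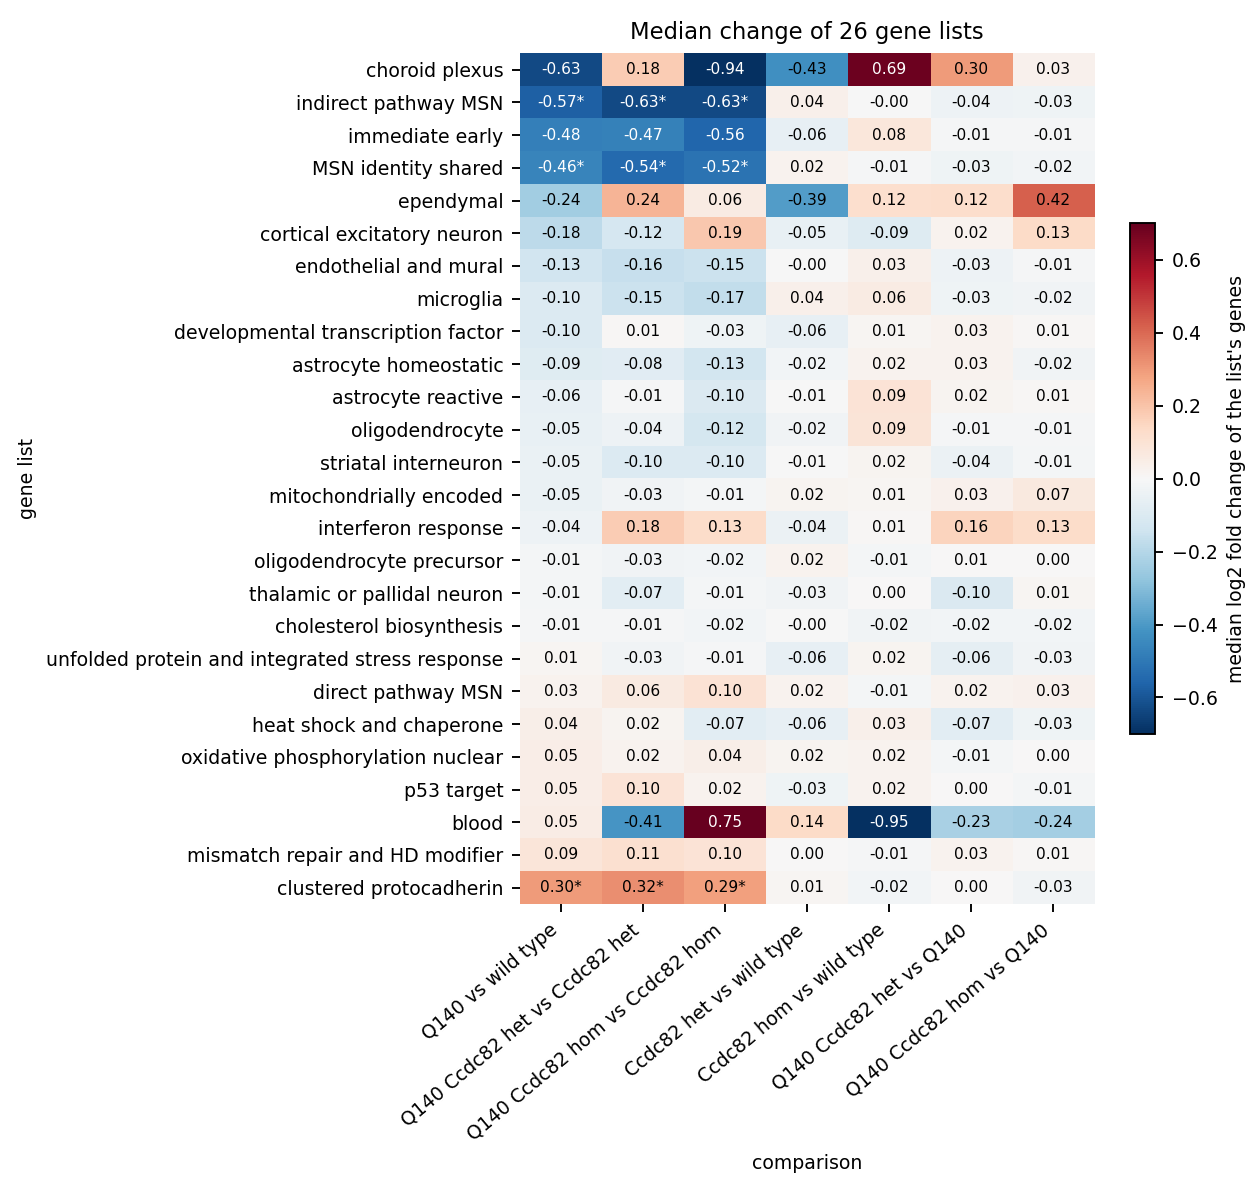
Median log2 fold change of 26 gene lists in 7 comparisons, with an asterisk where camera passed with an estimated correlation. The MSN identity, indirect pathway and clustered protocadherin lists carry an asterisk in all 3 Q140 comparisons, and no list carries one in the 4 Ccdc82 comparisons.

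Q140 was also compared with its control on the Ccdc82+/- and Ccdc82-/- backgrounds, which asks whether the effect of the expanded allele recurs when Ccdc82 is reduced. Penk fell by 1.18 ± 0.04 (SE) on the Ccdc82+/- and 1.07 ± 0.04 on the Ccdc82-/- background. Ddit4l fell by 1.90 ± 0.09 on each. All 24 MSN identity genes fell on both, with medians of -0.54 and -0.52. Of the indirect pathway genes 5 of 8 fell on both, or 7 adjusted over the list alone on Ccdc82+/- and 5 on Ccdc82-/-, with a median of -0.63 on each. Of 53 protocadherins 31 rose and 4 fell on Ccdc82+/- and 34 rose and 5 fell on Ccdc82-/-. These 3 lists passed camera also with an estimated correlation on both backgrounds, the highest adjusted p being 0.0115. In fits of only the groups compared 3 and 4 lists did. Of 19 microglia genes 16 and 14 fell, with camera adjusted p-values of 3.38e-05 and 3.78e-06 that became adjusted p = 0.207 and 0.129 with an estimated correlation. Of 17 endothelial and mural genes 11 and 9 fell, with camera adjusted p-values of 0.00213 and 0.000574 that became adjusted p = 0.207 and 0.129 in the same way.

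On the Ccdc82+/- background 6726 genes passed, 3524 higher and 3202 lower, and on the Ccdc82-/- background 6367, 3360 higher and 3007 lower. With the FPKM values these were 6309 higher and 1801 lower, and 5981 higher and 1731 lower. The 3 comparisons share no library, but they come from 1 fit with a shared dispersion per gene and a shared sex term. Their calls are therefore not fully independent. A total of 4434 genes passed in all 3, 2263 higher, 2171 lower and 0 of mixed direction in edgeR, out of 9114 that passed in at least 1. Between Q140 against wild type and the Ccdc82+/- background, 2609 genes were higher in both where independent lists would share 639.9, 2432 were lower in both against 528.9, and 2 were opposite against 1163. With the Ccdc82-/- background these numbers were 2541, 2342 and 1. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.768 with each background. Among the named genes, Sfmbt2, Dsp, Pcdh20, Tmc3, Rprm, Fam196b and Gm6089 were among the 10 largest rises in all 3 comparisons, and Gpx6, Mafa, Wnt8b, Cpne9, Sec14l3, Slc4a11 and Ddit4l among the 10 largest falls. Nts, the neurotensin gene, rose by 1.19 ± 0.22 and 1.17 ± 0.23 on the Ccdc82 backgrounds, and Ipcef1 rose by 1.11 and 1.28. Dsg2 rose by 1.30 and Vwa7 and Mas1 fell by 1.75 and 1.70 on the Ccdc82+/- background, and Egr2 fell by 1.72 on the Ccdc82-/- background. Ttr, a choroid plexus gene, stood at -2.67 ± 0.84 on the Ccdc82-/- background (adjusted p = 0.0115). This rested on 1 Ccdc82-/- male with high choroid plexus markers: without it and 2 other libraries that stood apart, the change was -0.38 and did not pass.

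**Figure D4:**
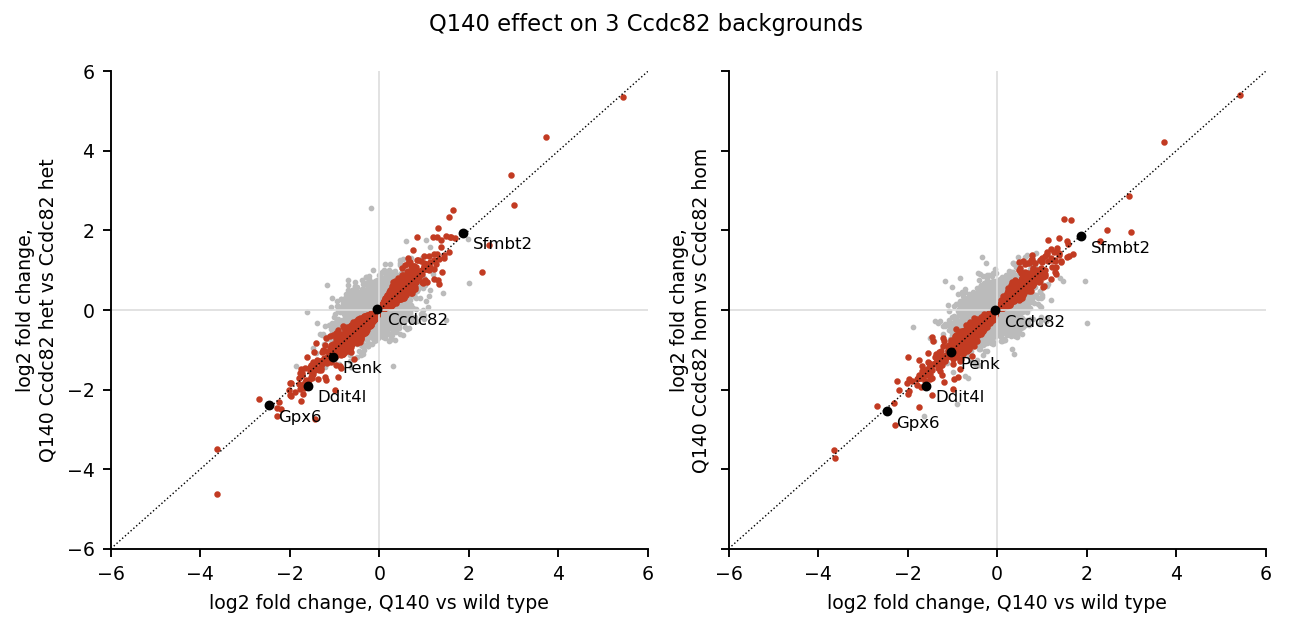
Log2 fold change of Q140 against wild type (horizontal axis) and of Q140 on the Ccdc82+/- and Ccdc82-/- backgrounds (vertical axes) for 19193 genes, with the 4434 genes past the threshold in all 3 comparisons in red and 5 genes named. The red genes lie in the lower left and upper right quadrants, as 0 of them changed direction.

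Ccdc82+/- and Ccdc82-/- mice were compared with wild type to ask what loss of Ccdc82 does on its own. Ccdc82 was the gene that passed in each comparison, with a log2 fold change of -0.51 ± 0.07 (SE, adjusted p = 1.03e-05) and -1.40 ± 0.07 (adjusted p = 1.32e-20). The MSN genes Penk and Ddit4l were at 0.04 ± 0.04 and 0.09 ± 0.08 in Ccdc82+/- mice and at -0.01 ± 0.04 and 0.08 ± 0.08 in Ccdc82-/- mice, and Htt was at -0.01 ± 0.03 and -0.05 ± 0.03. Unadjusted p-values under 0.05 numbered 628 and 804, where chance gives 959.7. The next gene in Ccdc82+/- mice was Gm42797 (adjusted p = 0.0569), which is named here after its value was seen. DESeq2, voom with quality weights and the FPKM fit each called 1 gene in both comparisons, and 0 of 45 genes within 5 Mb of Ccdc82 passed in edgeR, with 0 and 2 of them at an unadjusted p under 0.05.

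With Ccdc82 loss alone, gene lists passed camera with the preset correlation only. In Ccdc82+/- mice 6 lists passed: microglia and oxidative phosphorylation genes upward, with medians of 0.04 and 0.02, and chaperone, developmental transcription factor, choroid plexus and ependymal genes downward, with medians of -0.06, -0.06, -0.43 and -0.39. With an estimated correlation 0 passed and each had an adjusted p of 0.824. Without 3 libraries that stood apart, among them a Ccdc82+/- female with low ependymal markers, the ependymal and microglia lists did not pass, while the homeostatic astrocyte and oligodendrocyte lists did, so that 6 lists again passed. In Ccdc82-/- mice reactive astrocyte, microglia, oligodendrocyte and oxidative phosphorylation genes passed upward with medians of 0.09, 0.06, 0.09 and 0.02. With an estimated correlation these had adjusted p = 0.449, 0.551, 0.721 and 0.766. The largest medians in Ccdc82-/- mice were those of choroid plexus and blood genes, at 0.69 and -0.95, which did not pass (camera adjusted p = 0.794 and 0.121). The first rests on 1 male with a mean log2 CPM of choroid plexus markers of 2.69, where the other 7 libraries lay at -0.80 to -0.17, below the wild type mean of -0.147. Without the 3 libraries that stood apart, this male among them, the choroid plexus list passed camera beside the 4 lists named. Its markers in the 7 Ccdc82-/- libraries that remained lay below the wild type mean, unlike the upward median of 0.69 with all libraries. That mean includes wild type male 1, which stood apart at 0.76. The other wild type libraries, at -0.46 to 0.06, overlapped the 7 Ccdc82-/- libraries. No member of any of these lists passed over all genes, and over the list alone 2 protocadherins were lower in Ccdc82-/- mice. Exact permutation tests of list means gave 0 lists past the threshold and 0 at an unadjusted p under 0.05 in either comparison.

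Within Q140 mice, loss of 1 or 2 copies of Ccdc82 was compared with intact Ccdc82, the comparison that asks whether Ccdc82 modifies the Q140 state. Ccdc82 again was the gene that passed, at -0.43 ± 0.07 (SE, adjusted p = 0.000627) with 1 copy lost and -1.36 ± 0.07 (adjusted p = 1.63e-19) with 2. Penk was at 823.9 CPM ± 67.8 (SD, n = 8) in Q140, 765.1 ± 52.4 (n = 8) in Q140 Ccdc82+/- and 797.7 ± 44.8 (n = 7) in Q140 Ccdc82-/- mice. Ddit4l was at 12.2 CPM ± 1.96, 10.5 ± 1.56 and 10.3 ± 1.27, with log2 changes of -0.22 ± 0.09 and -0.23 ± 0.09 (SE) from Q140 that did not pass. Unadjusted p-values under 0.05 numbered 1101 and 712 against 959.7 by chance, and the next genes were Ptn (adjusted p = 0.754) and Pdk3 (adjusted p = 0.364), named after their values were seen. DESeq2, voom with quality weights and the FPKM fit each called 1 gene in both comparisons. Females alone and males alone gave 0 in edgeR for the loss of 1 copy.

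Interferon response genes were higher with reduced Ccdc82 in Q140 mice by camera with the preset correlation, with medians of 0.16 with 1 copy lost and 0.13 with 2 (adjusted p = 1.30e-07 and 0.000276). With an estimated correlation these became adjusted p = 0.797 and 0.783. Chaperone genes were lower in both (medians -0.07 and -0.03), MSN identity and unfolded protein genes were lower with 1 copy lost (medians -0.03 and -0.06), and microglia and blood genes were lower and ependymal genes higher with 2 copies lost (medians -0.02, -0.24 and 0.42). Their adjusted p with an estimated correlation lay between 0.783 and 0.867. With the replicate block in place of the sex term, only the chaperone and interferon lists passed with 1 copy lost, and only the interferon and ependymal lists with 2. Without 3 libraries that stood apart, among them a Q140 male with low ependymal markers, the MSN identity list with 1 copy lost and the ependymal and blood lists with 2 did not pass, and the choroid plexus list with 1 copy lost did. No member of these lists passed in edgeR over all genes or over the list alone. Of the lists that did not pass, 1 mitochondrially encoded gene was higher and 1 developmental transcription factor gene lower over the list alone with 1 copy lost. Exact permutation tests of list means gave 0 lists past the threshold, with 2 and 1 at an unadjusted p under 0.05.

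The Q140 signature score, built from the genes that changed with Q140 on the background not under test, condensed this comparison to 1 value per library. With genes chosen on the Ccdc82+/- background, wild type scored -0.93 ± 0.04 (SD, n = 8), Ccdc82-/- -0.93 ± 0.03 (n = 8), Q140 -0.43 ± 0.06 (n = 8) and Q140 Ccdc82-/- -0.42 ± 0.03 (n = 7). Q140 exceeded wild type by 0.50 (95% interval 0.45 to 0.54, exact permutation p = 0.000155), and Q140 Ccdc82-/- differed from Q140 by 0.01 (-0.03 to 0.06, exact permutation p = 0.630). With genes chosen on the Ccdc82-/- background, Q140 exceeded wild type by 0.51 (0.47 to 0.55, exact permutation p = 0.000155), and Q140 Ccdc82+/- differed from Q140 by 0.03 (-0.02 to 0.08, exact permutation p = 0.315). The Q140 effect on the score was 104% (95% interval 93.4 to 116) of its wild type size in Ccdc82-/- mice and 106% (95.6 to 118) in Ccdc82+/- mice. The permutation p of the difference was 0.529 and 0.305. The score genes were chosen on backgrounds with reduced Ccdc82, so genes whose Q140 response needs intact Ccdc82 could be left out. This tilts the score toward an undiminished Q140 effect, a limit that the gene by gene interactions do not share.

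**Figure D5:**
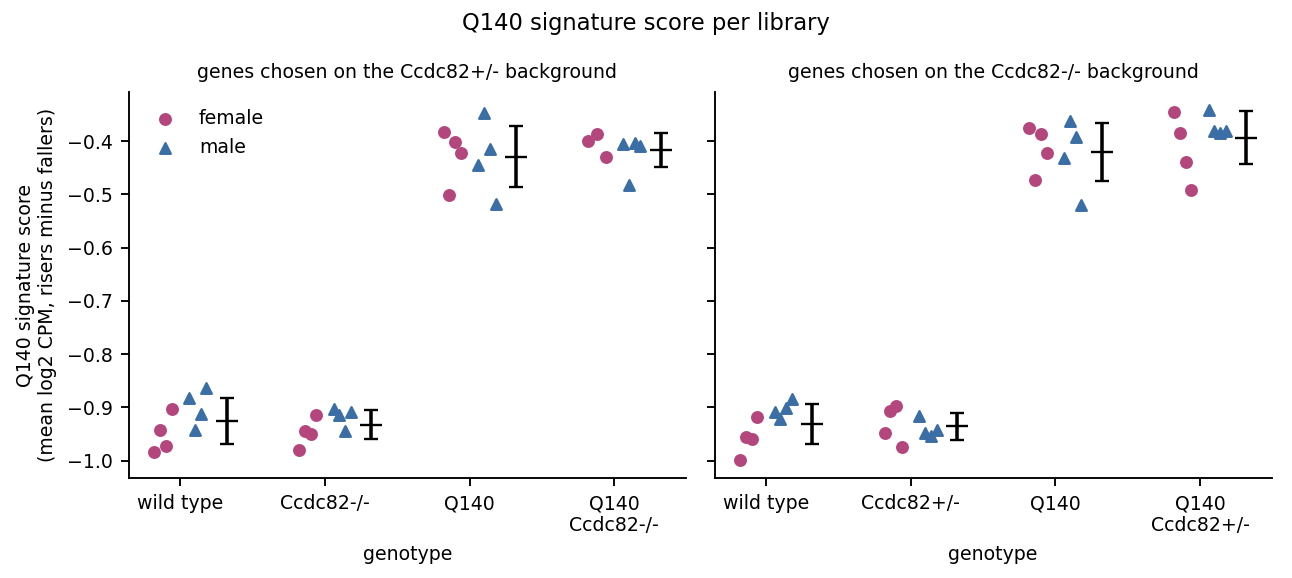
Q140 signature score per library (mean log2 CPM of the rising genes minus that of the falling genes) for 4 genotypes in each of 2 panels, with circles for females, triangles for males and a bar for the group mean ± SD. Q140 libraries lie 0.50 and 0.51 above wild type, and Q140 libraries with reduced Ccdc82 lie within 0.03 of Q140 on average.

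Interactions tested gene by gene whether the Q140 effect differed with Ccdc82 status. In edgeR 0 genes passed for Ccdc82+/- and 0 for Ccdc82-/-, with 1011 and 826 at an unadjusted p under 0.05 against 959.7 by chance. DESeq2 called 1 gene in the first, Gm10123 (edgeR adjusted p = 0.185), and 0 in the second, and voom with quality weights and the FPKM fit called 0 in both. The interferon response list had a median of 0.20 in the first and 0.18 in the second and the microglia list -0.06 and -0.08, past camera with the preset correlation. With an estimated correlation these had adjusted p = 0.831 and 0.849 for interferon genes and 0.831 and 0.592 for microglia genes. In all, 6 and 4 lists passed with the preset correlation and 0 with an estimated one. Averaged over both Htt genotypes, Ccdc82 was at -0.47 ± 0.05 (SE) with 1 copy lost and -1.38 ± 0.05 with 2, and it was the gene that passed. Unadjusted p-values under 0.05 numbered 758 and 642, and the median 95% half-width of a log2 fold change was 0.059 and 0.060. Of lists, 3 and 8 passed camera with the preset correlation and 0 with an estimated one.

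Females and males were compared in their response to Q140 and to loss of both Ccdc82 copies. In edgeR 0 of 19714 genes passed for each, with 1640 and 925 at an unadjusted p under 0.05 against 985.7 by chance. The gene nearest to the threshold for Q140 was Bves (adjusted p = 0.113), named after its value was seen, which voom with quality weights called. For the loss of both Ccdc82 copies that tool called 0.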

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

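The tests of the ependymal, MSN and Gm2420 patterns given here were chosen after those patterns had been seen. Libraries far from the others of their group were sought in 14 measures, 80 groups of libraries in all, of which chance alone would mark about 4. It marked 12.

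In 2 libraries, Q140 male 1 and Ccdc82+/- female 4, the mean log2 CPM of ependymal markers was far below the rest of the group, at -0.82 (others 0.78 to 2.09) and -1.07 (others 0.91 to 2.24). These are the low end of a variation over all libraries: after group and sex were taken out, the first principal component of the 1000 most variable genes (26.99% of their variance) followed the ependymal markers at a Pearson r of -0.992 over 47 libraries, and -0.988 without these 2. Low depth is argued against, since their total counts ranked 3 and 5 from the lowest of their 8 libraries. Less lining of the ventricle in the tissue taken is a candidate explanation: 51 motile cilium genes outside the marker list lay at a median of -0.67 and -0.99 log2 units from the group, against -0.52 to 0.68 in the other 45 libraries. As ependymal cells carry motile cilia, a lower share of them and a lower expression of their genes cannot be separated here, and no biological explanation was tested. Ccdc82+/- female 4 also had high oligodendrocyte markers, at 7.20 (others 6.76 to 6.94).

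All 24 MSN identity genes were lower in Q140 mice. A lower share of MSN, alike in both pathways and with expression per cell unchanged, is argued against. The direct pathway list changed by -0.045 and the shared list by -0.572. This difference of 0.527 log2 units (95% interval 0.455 to 0.598, exact permutation p = 0.000155, n = 8 per group) does not depend on scaling. The direct pathway mean joins opposite changes, with Drd1 at -0.57 and Isl1 and Tac1 at 0.37 and 0.17. An even loss offset by rises of some direct pathway genes within cells therefore stays open. A lower share of MSN would also raise the markers of the other cell types. The mean of 6 such lists changed by -0.087 log2 units with TMM scaling (95% interval -0.143 to -0.031, exact permutation p = 0.00746), but by -0.03 with FPKM (-0.089 to 0.029), so that test does not decide and an uneven loss of MSN stays open. Scaling as the whole cause is argued against, as the median of the 24 genes was -0.47 with RLE factors and -0.407 with FPKM, whose shift of all genes was 0.061. With the plate column in the fit the median was -0.464 and 24 of 24 genes passed. A loss of MSN, uneven or offset by such rises, and a lower expression of these genes within MSN cannot be told apart here.

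Gm2420, a pseudogene on chromosome 5 from 32720330 to 32736194 near Htt, had 0.83 CPM in Q140 and 0.017 CPM in wild type libraries, and was singled out after its values were seen. The first test asked whether reads had moved from its copies Pisd, Pisd-ps1 and Pisd-ps2, and it did not decide, since their sum was 2.61 CPM higher in Q140 (exact permutation p = 0.152, n = 8 per group). Pisd alone was then picked because its group means were seen to be lower, and it was lower in Q140 carriers by -0.721 CPM (95% interval -1.29 to -0.135, permutation p = 0.031) beside a Gm2420 rise of 0.958 CPM; values that gave the idea cannot support it. Another strain's DNA carried around Htt was not decided either: 10 of 146 genes within 5 Mb of Htt changed by at least 0.3 on all 3 backgrounds, a count that 42.2% of windows elsewhere reached. Moved reads, strain DNA and an effect of the Q140 allele cannot be told apart with these tests.

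The other marked libraries are given as values. Choroid plexus markers had a mean log2 CPM of 2.69 in Ccdc82-/- male 1 (others -0.80 to -0.17), 0.76 in wild type male 1 (others -0.46 to 0.06) and 0.23 in Ccdc82+/- female 2 (others -0.85 to -0.34). Blood markers were at -4.38 in Q140 female 3 (others -1.10 to 1.82) and -3.99 in Q140 Ccdc82+/- female 2 (others -0.57 to 1.08). Immediate early genes were at 5.14 in Ccdc82-/- female 1 (others 5.59 to 5.97) and 3.99 in Q140 Ccdc82+/- female 1 (others 4.82 to 5.46). Q140 Ccdc82+/- male 1 had 58.8 M counts (others 42.8 to 49.8), and wild type female 2 had 6.02% of counts from mitochondrially encoded genes (others 5.57 to 5.74).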

How the results depend on the processing

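The fits without 3 libraries that stood apart and with the identifier number as a random block were chosen after the data had been seen. No call past the threshold reversed direction under any alternative, though differences that passed in neither fit could change sign, such as the signature score of Ccdc82+/- against wild type, at -0.005 in the main analysis and 0.0264 in females alone. Of the results that answer a comparison 203 values stayed the same, which for a count of genes or lists means within a factor of 1.5 of the main count and for other values the same side of the threshold, 5 became stronger and 30 weaker. For 50 pairs of a named gene and a comparison, 579 of 596 alternative values kept their side of the threshold and 17 became weaker. Other genes named in the Results, such as Wdfy1 and Hoxa7, were not among these pairs. For Q140 against wild type, C1qc no longer passed in 2 alternatives, and Cd68, Kdr, S100b, Homer1, Npas4 and Htt in 1 each. Fewer libraries lowered the counts of Q140 genes in edgeR: females alone gave 4321 and males alone 3922 for Q140 against wild type, females alone 3324 on the Ccdc82+/- background, and females alone 3452 and males alone 3783 on the Ccdc82-/- background. Ccdc82 itself no longer passed for Ccdc82+/- against wild type in males alone (0 genes), at a log2 change of -0.474 ± 0.09 (SE) where all libraries gave -0.514 ± 0.066. Nor did it for Q140 Ccdc82+/- against Q140 in females alone (0) or males alone (0), at -0.49 ± 0.082 and -0.376 ± 0.09 where all libraries gave -0.434 ± 0.066. The fold stayed within these errors of its main value while the errors grew with fewer libraries. Ttr in the Q140 effect on the Ccdc82-/- background did not pass in 6 alternatives. With the plate column as a factor 2 genes passed for Ccdc82+/- against wild type and 1, Gm42797, for the interaction with Ccdc82+/-. DESeq2 called 1, Gm10123, in that interaction, and voom with quality weights called 1 in the sex interaction for Q140. The cause of these calls was not tested. With an estimated correlation 3 lists passed in each of the 3 Q140 comparisons in the fit of all libraries (0, 3 and 4 in fits of only the groups compared), and 0 in each of the 8 Ccdc82, interaction and average comparisons, where fry also gave 0. With the replicate block in place of the sex term 6647 genes passed for Q140 against wild type, 6739 and 6276 on the Ccdc82+/- and Ccdc82-/- backgrounds, 1 in each Ccdc82 comparison and 0 in each interaction. The lists past camera with that block were 2 for Q140 Ccdc82+/- against Q140 and 2 for Q140 Ccdc82-/- against Q140. Without the 3 libraries, 3 lists passed for Q140 Ccdc82-/- against Q140 and 5 for the average Ccdc82+/- effect. Over the alternatives with all libraries, Q140 against wild type ranged from 5755 to 7787 genes. The FPKM fit gave 74.9% of these as higher where TMM gave 52.4%. Depth limits genes with few counts: the median 95% half-width over the 13938 genes with a mean log2 CPM of at least 1 was 0.083 to 0.087 between 2 groups and up to 0.121 in an interaction.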

Other observations

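The tests of the identifier number were chosen after the data had been seen, and the genes named here for the sex difference were chosen after their values were seen. The gene span tests and the regroupings were planned.

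Females and males differed at many genes, over all 6 genotypes. With sex as the term tested, 1664 genes passed between 24 males and 23 females, 774 higher and 890 lower in males. Of these 1585 lay on autosomes, 71 on chromosome X and 8 on chromosome Y. Autosomal differences were small, with a median absolute log2 change of 0.103 and 6 genes at 1 or more. Tmprss6, a protease gene, was at 2.56 CPM ± 1.54 (SD) in males and 1.31 ± 0.819 in females, a log2 difference of 0.998 ± 0.09 (SE). Its level was also lower in Q140, at 0.87 CPM where wild type had 3.05. The SD values given here for each sex span all 6 genotypes and so include changes with Q140. Dsp, which also rose in Q140, was at 1.85 CPM ± 1.18 in males and 3.80 ± 2.22 in females, a difference of -1.11 ± 0.12. The protocadherin gene Pcdhb6 differed by -0.44 ± 0.04, the microglial gene Fcrls by -0.30 ± 0.03 and the zinc finger gene Zfp677 by 0.43 ± 0.06. Regrouping the sexes gave as many autosomal genes in 1 of 60 splits, the real one, which had 1576 where the highest other had 1. These splits moved single libraries. Each number in the sample identifiers belonged to females only or to males only, and libraries with the same number correlated. What goes with the numbers was therefore not separated from sex, and this test does not exclude chance.

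Sample identifiers hold 1 of 19 numbers, which libraries of the same or of different groups can share and whose meaning the labels do not give. After group and sex were taken out, 38 pairs of libraries with the same number in different groups correlated by 0.115 on average, and 882 other pairs by -0.005, a difference of 0.12 (one-sided permutation p = 3e-04, 10000 permutations). Each number belonged to females only or to males only, which argues against numbers given to whole litters of both sexes. A shared cage, shared handling or littermates of the same sex are candidate explanations, and the labels cannot separate these. Pairs with the same number were thus of the same sex, which the permutations of the numbers did not keep. With the number as a random block 6735 genes passed for Q140 against wild type and 1 in each Ccdc82 comparison. The consensus correlation of libraries with one number in that fit was 0.147. The exact permutation tests took libraries as exchangeable and were not repeated with the number.

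Whether expression followed the length of genes was tested on the 1257 longest and 1257 shortest protein coding genes, with spans of at least 150.6 kb and at most 5.18 kb. The long genes changed relative to the short ones by -0.0127 log2 units in Q140 against wild type, and by 0.0239 and 0.0137 on the Ccdc82+/- and Ccdc82-/- backgrounds (exact permutation p = 0.274, 0.193 and 0.690). Upper 95% bounds reached 0.062 on both Ccdc82 backgrounds, beyond the 0.05 set in advance, so the test was left open; that the bounds and not the values should stay within 0.05 was decided after the values were seen. With loss of both Ccdc82 copies the change was -0.0395 (95% interval -0.0877 to 0.0087, exact permutation p = 0.0491) without Q140 and -0.0132 (exact permutation p = 0.257) with it, which leaves that question open too.

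Random regroupings of the libraries, fitted on the compared groups alone, gave counts of genes to set beside the real ones. A count as large was reached by 1 of 100 regroupings, the real one, for Q140 against wild type (6309 genes, highest other 1897), for Q140 on Ccdc82+/- (6591, highest other 3373) and for Q140 on Ccdc82-/- (5534, highest other 4473). This argues against chance for these, at 1 of 100, the lowest share that the test can give. The regroupings took libraries as exchangeable and did not keep those with the same identifier number together. Each Ccdc82 comparison had a single gene. A count of 1 gene was reached by 2 of 100 for Ccdc82+/- against wild type (highest other 4). It was reached by 4 of 100 for Q140 Ccdc82-/- against Q140 (highest other 3). For Ccdc82-/- against wild type 6 of 100 reached it (highest other 109), and for Q140 Ccdc82+/- against Q140 7 of 100 (highest other 256). As other regroupings gave as many genes or more in each, the count alone does not exclude chance. Ccdc82 itself had an exact permutation p of 0.000155 in each of these Ccdc82 comparisons. Nor does the count exclude chance for the average Ccdc82+/- effect (5 of 60, highest other 11) or the average Ccdc82-/- effect (4 of 60, highest other 32). All 60 reached the 0 genes of each interaction, with 16 and 789 as the highest other, and all 100 the 0 genes of each sex interaction, with 4 and 1.

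The number of lists past camera with the preset correlation was within chance in all 11 comparisons. Counts as large came from 37 of 100 regroupings for Q140 against wild type (9 lists, highest other 13), 53 for Q140 on Ccdc82+/- (8, highest other 15) and 23 for Q140 on Ccdc82-/- (11, highest other 15). For Ccdc82+/- and Ccdc82-/- against wild type they came from 38 (8 lists, highest other 14) and 94 (4, highest other 18), and within Q140 from 92 (4, highest other 16) and 75 (6, highest other 14). Of 60 regroupings, 44 and 56 reached the 6 and 3 lists of the interactions (highest other 12 and 14), and 58 and 26 the 3 and 8 lists of the averages (highest other 14 for both). With an estimated correlation, 0 of the other 99 regroupings reached the 3 lists of Q140 on Ccdc82+/- (highest other 0) or the 4 lists of Q140 on Ccdc82-/- (highest other 1). The other 9 comparisons had 0 lists, which all regroupings reach.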
